A study of Mus musculus with 25 samples.

How the data were processed

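Single cells of mouse primary somatosensory cortex had been captured in droplets and counted by RNA molecule. Per the labels' protocols, sections of somatosensory cortex were cut into an upper region, layer V and layer VI, and 1 male and 1 female mouse were used per time point, with red fluorescent subcerebral neurons (a Fezf2-driven reporter) as the landmark of layer V, and green fluorescent oligodendrocyte-lineage cells (a Plp1 reporter) were sorted before 10x capture. The upper region is layers 1 to 4 in the protocol text, II-IV in the titles and II-III in some cell names; it is called layers II-IV here. Xist was nearly absent from 2 sorted sets and from P7 whole S1, which goes against a female mouse in them. The labels give version 2 of the 10x chemistry for replicate 1 and version 3 for replicate 2, so chemistry and replicate number are one factor in the sorted libraries. The whole S1 libraries are of C57Bl/6 mice and their labels name all cell types, but they carry the same text on dissection and sorting. If their cells had been sorted, the class shares at P7 and P21 would describe the sort as well as the tissue. Papain was used to free the cells, a step that can itself induce immediate early genes.

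The deposited values are raw UMI counts per gene and cell, and the authors left them unnormalized, since each cell sums to the total count given beside it. The deposited cell tables give the percent of each cell's counts from mitochondrial genes and, for whole S1, the authors' doublet score per cell; its caller is not given in the sources used here. Cell Ranger (version not given in the sources used here), Seurat 4.0.0 and the mm10 build are named per the submitters' processing notes, without their roles. Only cells the authors kept enter, with the authors' final class names, and the filters they applied are not given in the sources used here. No doublet caller was run here, no cell was removed and no share of free RNA from other cells was estimated, so low levels of another class's transcripts, such as myelin genes in OPC, may be carried over. Classes were read by their usual names: OPC (precursors), COP (committed precursors), NFOL (newly formed), MFOL (myelin-forming) and MOL (mature oligodendrocytes, split into MOL_A, MOL_B and MOL_C in the sorted cells). The neuron classes were UL_CPN and DL_CPN (upper and deep layer callosal projection neurons), L4, CThPN (corticothalamic), SCPN (subcerebral), NP/SCPN and L6b_Subplate; the P7 names for stellate layer 4, near-projecting and subplate cells were matched to the P21 ones. The whole S1 tables hold projection neurons and the oligodendrocyte lineage, so shares there are of deposited cells. A filter or a class call by the authors that differed between libraries would move shares and sums alike.

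Depth differed by chemistry and age. Median UMIs per cell ran from 2163 to 5587 in the sorted replicate 1 libraries, from 6011 to 16819 in replicate 2, from 16016.5 to 17162 in P7 whole S1 and from 8957 to 10290 in P21 whole S1. Sorted libraries held 700 to 3504 cells.

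Counts were summed per library, over all cells or per class, and a sum needed at least 10 cells. Sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr for low counts, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3; the standard error given is the log2 difference divided by the square root of F. The 3 layers of a set were cut from the same mice per the labels, so the mouse set (age and replicate number) entered as a block in the layer comparisons. Age was fitted as log2 of the age in days over the 6 sets (layers summed) with the chemistry as a covariate, and its interaction with layer VI against layers II-IV with the set as a block. P21 against P7 had no covariate. Deep against upper neurons had the library as a block, and the change of that difference between the ages was added after seeing the data. Class shares were compared by exact sign-flip tests within sets and exact permutation tests between ages, two-sided. CPM are counts per 1e6 of each sum. Limits and intervals have 95% confidence.

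Before the data were examined, the groups, the tests, their covariates, most alternatives, the lists and the rule for naming genes were fixed. The rule names, per comparison, the 10 genes with the smallest p per direction among those that passed with the same sign in every set or library pair (between ages, no overlap of libraries), leaving out unnamed gene models, ribosomal and mitochondrial genes. It adds up to 4 members of each called list, Fgf18, Ncam1 and Rspo3 where neurons were compared, the receptors Fgfr1, Fgfr2, Fgfr3, Lgr4, Lgr5 and Lgr6 where oligodendrocytes were, and the 5 smallest p per direction where no gene passed. The text gives a part of these, and genes without a value, such as Lgr6, did not pass the filter on low counts. The 23 lists were OPC, precursor and newly formed, and mature oligodendrocyte markers, myelin genes, cholesterol synthesis, immediate early and dissociation genes, interferon and MHC class I genes, neuronal cues and their receptors. They also held markers of upper callosal, layer 4, layer 5 subcerebral, layer 6 corticothalamic, layer 6b and near-projecting, and inhibitory neurons, and of neurons, astrocytes, microglia, endothelial, and mural and fibroblast cells, with mature neuron, immature neuron and cell cycle genes. Some genes stand in several lists. Lists were tested with limma 3.58.1 camera with a preset correlation of 0.01 between genes, and again with an estimated correlation. Of 62 list calls in the 8 comparisons with all cells or all neurons, 1 held with an estimated correlation.

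Alternatives were DESeq2 1.42.0 as the tool, its size factors in edgeR, no filter on low counts, counts thinned to the smallest total, no block, each set or library left out, 1 chemistry only, P30 and P90 only, 1 class only and an immediate early gene score as a covariate; for shares, log odds and another denominator. The edgeR and camera steps were tested on simulated summed counts with 200 changed genes in 24 comparisons. Each gene was drawn on its own from its fitted mean and dispersion, so class names, summing and correlation between genes were not tested. For log2 changes of -2, -1, 1 and 2, the median share recovered over comparisons was 97.9, 84.7, 91.9 and 100%. It was 93.9, 80.0, 84.0 and 93.9% for layer VI against layers II-IV on 13735 simulated genes. For the age trend, on 13689 genes, it was 12.5, 0, 10.0 and 82.0%, of 16, 37, 50 and 50 changed genes that passed the filter. Changes in the age trend and in its interaction with layer were given per doubling of age. Recovery there thus does not show the power for a log2 change of that size between P7 and P90. Unchanged genes made up 2.04% (age trend) to 9.78% (COP, P21 against P7) of the simulated calls at an adjusted p under 0.05. They made up 4.92% for layer VI against layers II-IV and 8.60% for layer VI against layer V. The threshold thus let through more unchanged genes than its nominal rate in several comparisons. Replicate libraries were compared by a chi-square test of their counts over genes. Per degree of freedom it ran from 1.19 to 5.13 over 93 pairs of whole S1 sums and from 10.1 to 85.6 over 9 sorted pairs. Sorted replicates also differ in chemistry, and the whole S1 values cannot show whether those libraries came from separate animals. Each library was counted once. Genome places are from GENCODE vM21 on GRCm38, matched by symbol for all 337 genes named. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest. Genes that overlap or have near-identical copies may share counts, and strand handling is not given in the sources used here.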

Results

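The libraries held single-cell RNA counts from mouse primary somatosensory cortex (S1), the cortical field that receives touch signals. In 18 libraries, cells of the oligodendrocyte lineage, which makes the myelin around axons, had been sorted from dissected cortical layers. They formed 6 mouse sets, each with 1 library of layers II-IV, 1 of layer V and 1 of layer VI, at postnatal day 7 (P7, 1 set), P14 (1 set), P30 (2 sets) and P90 (2 sets). The other libraries held whole S1 at P7 (3 libraries) and P21 (4 libraries), with projection neurons and oligodendrocyte-lineage cells in the deposited tables. The 12 sorted replicate 1 libraries, made with version 2 of the 10x chemistry, held 22172 cells and 3048696 to 13012608 unique molecular identifiers (UMIs) each. The 6 replicate 2 libraries, made with version 3, held 16272 cells and 16283754 to 45359860 UMIs each. Whole S1 gave 15985 cells at P7 and 16953 at P21, with 82961081 to 86143314 and 39646137 to 46475960 UMIs per library. Nothing in the labels says that the whole S1 libraries of an age came from separate animals, so their p-values measure only the spread between these libraries, which may be technical.

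The makeup of the sorted lineage by layer was compared first. Oligodendrocyte precursor cells (OPC), the dividing cells from which oligodendrocytes form, made up 40.0 ± 29.2% in layer VI, 53.9 ± 38.1% in layer V and 62.6 ± 34.6% in layers II-IV (SD, n = 6 sets). The mature class named MOL_B made up 9.55 ± 8.03% in layer VI, 1.60 ± 1.82% in layer V and 0.698 ± 0.822% in layers II-IV, and newly formed oligodendrocytes (NFOL) 2.56 ± 3.35% in layer VI, 1.48 ± 2.14% in layer V and 1.16 ± 1.67% in layers II-IV. Within sets, layer VI minus layers II-IV was -22.6 ± 12.6 percentage points for OPC (lower in 5 of 6 sets) and 8.86 ± 7.52 for MOL_B (higher in 5, lower in 0). It was 1.40 ± 1.86 for NFOL (higher in 5), with a mean from 0.663 to 1.68 when 1 set was left out. Layer VI minus layer V was -13.9 ± 11.8 for OPC and 7.96 ± 6.51 for MOL_B. Each of these had a two-sided exact sign-flip p of 0.0625 and an adjusted p of 0.219 over 21 tests. The smallest p that 6 sets allow is 0.0312, and 0 of the tests passed. For MOL_B, with a difference of 0 in P7 replicate 1, the smallest possible p was 0.0625, the value found. After adjustment over 21 tests a single test at 0.0312 could not pass either, so these tests cannot decide whether shares differed. In an edgeR test of cell numbers with the set as a block, chosen after seeing the data, MOL_B passed in layer VI against layers II-IV (log2 ratio 3.63, adjusted p = 2.92e-05) and against layer V (log2 ratio 2.54, adjusted p = 0.000983).

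By chemistry, layer VI minus layers II-IV for OPC was -18.1 (P7), -23.3 (P14), -29.8 (P30) and -28.1 points (P90) in replicate 1. In replicate 2 it was -36.2 (P30) and 0.0413 (P90), where the 3 libraries of P90 held 1 OPC among 8177 cells. For MOL_B the replicate 1 differences were 0, 0.0557, 10.7 and 9.32 points at P7, P14, P30 and P90, and the replicate 2 differences 18.1 and 15.0 at P30 and P90. The abundant mature class MOL_A made up 31.2 ± 29.1% in layer VI, 31.9 ± 36.5% in layer V and 25.3 ± 33.7% in layers II-IV, with no direction shared by the sets. The shares are of sorted cells, so the gate and the filter on cells can set them.

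**Figure D1:**
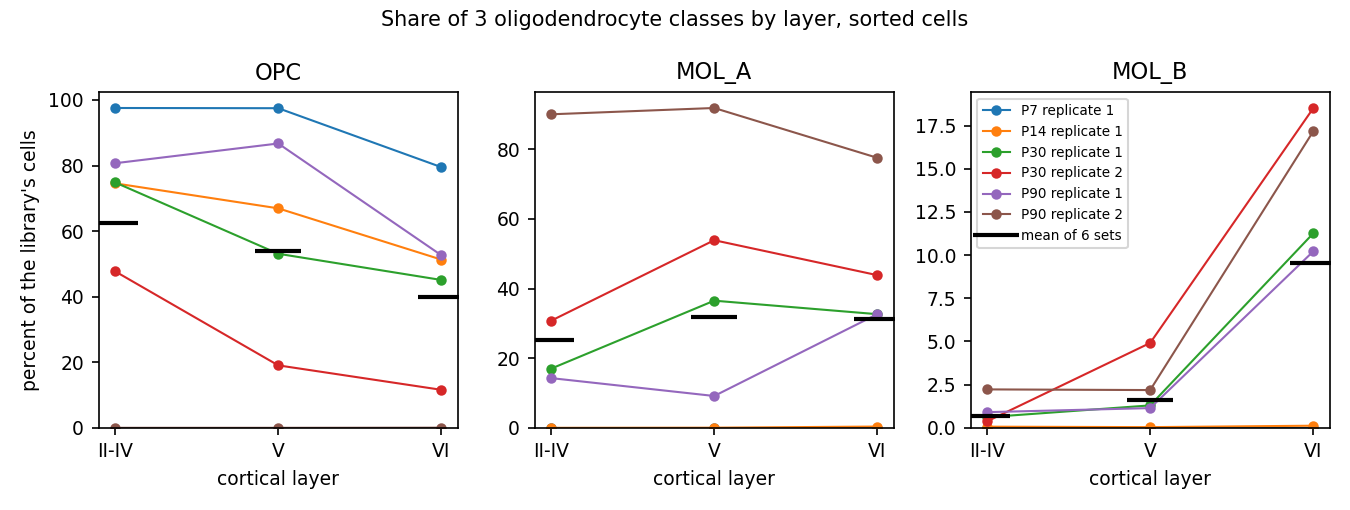
Percent of each library's cells (vertical axis, a separate scale in each panel) that were OPC, MOL_A or MOL_B, by cortical layer (horizontal axis). Each line joins the 3 layers of 1 mouse set and black bars give the mean of 6 sets; mean MOL_B was 9.55% in layer VI and 0.698% in layers II-IV.

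The next comparison asked which genes differed between oligodendrocyte-lineage cells of layer VI and of layers II-IV, with all sorted cells summed per library. Class shares, which also differed between these layers, enter such sums. Klk6, a secreted protease of mature oligodendrocytes (chromosome 7, 43824499 to 43832030), was higher in layer VI by 4.13 ± 0.35 on the log2 scale (SE, n = 6 sets; edgeR adjusted p = 0.00017), at 58.2 ± 57.1 against 4.38 ± 6.53 CPM (counts per 1e6 of the library, SD). It was higher in 5 of 6 sets. In MOL_A cells alone, Klk6 in layer VI and layers II-IV was at 58.4 and 24.3 CPM in P30 replicate 1 and 61.3 and 39.3 in P30 replicate 2. It was at 16.8 and 5.34 in P90 replicate 1 and 11.8 and 1.59 in P90 replicate 2. Anxa5, a calcium-dependent phospholipid-binding protein (chromosome 3, 36448923 to 36475894), was higher by 2.08 ± 0.22 (adjusted p = 0.000332) and Hopx, a small homeodomain protein (chromosome 5, 77086988 to 77115121), by 3.32 ± 0.49 (adjusted p = 0.00146). Pdgfa, a growth factor that drives OPC division (chromosome 5, 138976014 to 138997370), rose by 0.99 ± 0.11, from 101 ± 54.7 to 192 ± 82.0 CPM. The imprinted zinc-finger gene Peg3 (chromosome 7, 6703892 to 6730431) differed by -0.82 ± 0.08 (adjusted p = 0.000211) and was lower in layer VI in 6 of 6 sets. All genome places are on GRCm38 and enclose whole protein-coding genes.

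Markers of OPC and genes of myelin moved apart between layer VI and layers II-IV. Of 10 OPC markers 10 fell and 0 rose, also 10 adjusted over the list alone, among them the growth factor receptor Pdgfra (-1.05 ± 0.20) and the proteoglycan Cspg4 (-1.28 ± 0.19). The list's camera adjusted p was 4.47e-05, with adjusted p = 0.301 with an estimated correlation. Of 20 myelin genes 17 rose and 0 fell (18 rose adjusted over the list alone; camera adjusted p = 2.23e-06), such as Fa2h, which makes myelin lipids (1.08 ± 0.21), and the transcription factor Myrf (0.96 ± 0.22); adjusted p = 0.301 with an estimated correlation. Class shares enter these sums: within the mature classes, chosen after seeing the data, 0 of 19 myelin genes rose by edgeR in MOL_A, MOL_B or MOL_C, and 1, 2 and 0 fell (list medians 0.00034, -0.0262 and -0.0113). Of 18 mature oligodendrocyte markers 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00023, and adjusted p = 0.301 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 23 cases and fell in 0 (21 rose adjusted over the list alone; camera adjusted p = 5.61e-09), including Hmgcs1 (0.74 ± 0.13) and the feedback regulator Insig1 (0.81 ± 0.14); adjusted p = 0.301 with an estimated correlation. Of 24 immediate early and dissociation genes, which respond within minutes to activity or stress, 15 rose and 0 fell (16 rose adjusted over the list alone; camera adjusted p = 2.85e-06), among them Egr3 (3.16 ± 0.42) and Atf3 (2.31 ± 0.29); adjusted p = 0.301 with an estimated correlation.

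Genes of other programmes were lower in the summed cells of layer VI, which also differed in class shares. Interferon and MHC class I genes fell in 9 of 17 cases (11 adjusted over the list alone; camera adjusted p = 0.00129), such as Ifit3 (-2.26 ± 0.30). Within classes 1 of 14 fell in OPC, 2 of 10 in MOL_A and 0 by edgeR in COP, NFOL, MFOL, MOL_B and MOL_C. Astrocyte markers fell in 8 of 14 (8 adjusted over the list alone; camera adjusted p = 0.00129), such as the sodium pump subunit Atp1a2 (-0.89 ± 0.18). Both had adjusted p = 0.301 with an estimated correlation. Of 17 mature neuron genes 12 fell and 0 rose (13 fell adjusted over the list alone; camera adjusted p = 0.000263, and adjusted p = 0.301 with an estimated correlation), such as the synaptic protein gene Snap25 (-0.86 ± 0.19). In the mature oligodendrocyte classes alone, chosen after seeing the data, Snap25 was at 0.06 and Myrf at -0.01. Among receptors for the growth factor Fgf18, Fgfr1 fell by 0.77 ± 0.14 and Fgfr2 rose by 1.27 ± 0.28, while Fgfr3 differed by -0.19 ± 0.22 (adjusted p = 0.552). Within MOL_A neither passed, with Fgfr2 at -0.0138 (adjusted p = 0.966) and Fgfr1 at -0.57 (adjusted p = 0.158), and nor did either within OPC (1.37 and -0.28, adjusted p = 0.157 and 0.233). Of receptors for R-spondins, Lgr4 rose by 0.66 ± 0.19 (adjusted p = 0.019) and Lgr5 differed by -0.35 ± 0.23 (adjusted p = 0.27). Within MOL_A Lgr4 was at 0.21 (adjusted p = 0.523).

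By edgeR, 4057 of 13954 genes passed, 1780 higher and 2277 lower, and 4466 by DESeq2. Within chemistry 2248 passed in replicate 1 and 754 in replicate 2. Without the mouse set as a block 0 passed (376 at unadjusted p under 0.05). Leaving out P14 replicate 1 gave 2294 and leaving out P30 replicate 2 gave 1918; with an immediate early gene score as a covariate 217 passed, and with counts thinned to the smallest total 381.

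Between layer VI and layer V, immediate early genes led the difference. Egr3, an activity-induced transcription factor (chromosome 14, 70077203 to 70082614), was higher in layer VI by 3.76 ± 0.46 (n = 6 sets; edgeR adjusted p = 0.0067), and Csrnp1 (chromosome 9, 119971163 to 119984658) by 1.17 ± 0.15 (adjusted p = 0.0067). The stress-response factor Atf3 was higher by 2.07 ± 0.29, which in OPC alone was at -0.17. Pdgfa rose by 0.78 ± 0.11, Anxa5 by 1.33 ± 0.21 and Klk6 by 1.94 ± 0.30 (adjusted p = 0.0143, 0.0242 and 0.025), while Peg3 fell by 0.50 ± 0.08 (adjusted p = 0.025). Of 24 immediate early and dissociation genes 5 rose and 0 fell (15 rose adjusted over the list alone; camera adjusted p = 9.52e-11), and of 18 mature oligodendrocyte markers 2 rose (8 adjusted over the list alone; camera adjusted p = 0.00102). Both had adjusted p = 0.473 with an estimated correlation. Class shares enter the sums, with OPC 13.9 points lower and MOL_B 7.96 points higher in layer VI (exact sign-flip p = 0.0625 for each). OPC markers were shifted down (0 passed, 5 of 10 lower adjusted over the list alone; camera adjusted p = 3.87e-05) and myelin genes up (0 passed, 2 of 20 higher adjusted over the list alone; 1.65e-06), with adjusted p = 0.473 with an estimated correlation. Cholesterol synthesis was shifted up (0 passed, 3 of 23 higher adjusted over the list alone; camera adjusted p = 8.87e-06, and adjusted p = 0.496 with an estimated correlation). Interferon and mature neuron genes were shifted down (0 passed, 4 of 17 and 2 of 17 lower adjusted over the list alone; camera adjusted p = 0.00709 and 0.00182), with adjusted p = 0.473 with an estimated correlation. By edgeR 17 genes passed, 16 higher and 1 lower, 398 by DESeq2, and with DESeq2's size factors in edgeR 19 higher and 5 lower. Within chemistry 129 passed in replicate 1 and 12 in replicate 2. Leaving out 1 set gave 0 (P30 replicate 1), 3 (P90 replicate 1), 4 (P90 replicate 2), 6 (P14 replicate 1) or 69 genes (P7 replicate 1); 0 passed without the block or with the immediate early score (114 and 1216 at unadjusted p under 0.05).

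Between layer V and layers II-IV no gene passed over all lineage cells. By edgeR 0 of 13954 passed (1575 at unadjusted p under 0.05), also 0 within each chemistry (639 and 1293 at unadjusted p under 0.05), and 1 passed by DESeq2. The smallest p on the higher side included Klk6 at 2.19 ± 0.34 (adjusted p = 0.335), and Ankrd34a was at -2.15 ± 0.42 (adjusted p = 0.421; n = 6 sets, edgeR). Lgr4 was at 0.44 ± 0.19, Fgfr1 at -0.31 ± 0.14 and Fgfr2 at 0.39 ± 0.28 (adjusted p = 0.423, 0.426 and 0.568). Cholesterol synthesis genes were shifted up as a list (camera adjusted p = 1.06e-08, and adjusted p = 0.53 with an estimated correlation), with Hmgcs1 at 0.39 ± 0.13 and 0 of 23 passing, also adjusted over the list alone. Myelin genes and mature oligodendrocyte markers were shifted up (camera adjusted p = 0.00641 and 0.00451; 0 and 2 passing adjusted over the list alone), and OPC markers, cell cycle genes and interferon genes down (camera adjusted p = 0.00649, 0.00649 and 0.0165; 0 passing adjusted over the list alone). These 5 had adjusted p = 0.542 with an estimated correlation. Markers of other cells were shifted down as well, namely of astrocytes (0.000733), mature neurons (0.00649), upper layer callosal neurons (0.0351) and layer 6b or near-projecting neurons (camera adjusted p = 0.025), with 0, 1, 2 and 3 genes lower adjusted over the list alone. All 4 had adjusted p = 0.53 with an estimated correlation.

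Within MOL_A cells alone, the mature class with most cells, several genes were higher in layer V than in layers II-IV and higher again in layer VI. The mean share of MOL_B was also highest in layer VI. MOL_B cells counted among MOL_A were not excluded as a source of these differences or of the gene counts within MOL_A. S100b, a calcium-binding protein (chromosome 10, 76253853 to 76261159), rose in layer VI against layers II-IV by 1.83 ± 0.09 (n = 4 sets; edgeR adjusted p = 8.28e-17), at 86.4 ± 37.6 against 26.8 ± 11.8 CPM. In layer V against layers II-IV it rose by 0.89 ± 0.09 (adjusted p = 2.68e-07), at 46.0 ± 24.0 CPM in layer V, and in layer VI against layer V by 0.93 ± 0.09. Hopx rose by 2.80 ± 0.19 and 1.21 ± 0.21 in the same comparisons, and Enpp6, a choline phosphodiesterase known from newly formed oligodendrocytes, by 1.75 ± 0.10 and 0.89 ± 0.10. Fos, the best known immediate early gene (chromosome 12, 85473890 to 85477273), rose in layer VI against layers II-IV by 1.92 ± 0.11 (adjusted p = 7.92e-16), at 1195 ± 227 against 325 ± 116 CPM, and against layer V by 1.86 ± 0.11. Timp3, an inhibitor of metalloproteinases, and Ptgds, prostaglandin D synthase, were lower in layer VI than in layers II-IV (-1.84 ± 0.16 and -1.58 ± 0.19). Fgfr2 differed by -0.01 ± 0.07 (adjusted p = 0.966).

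**Figure D2:**
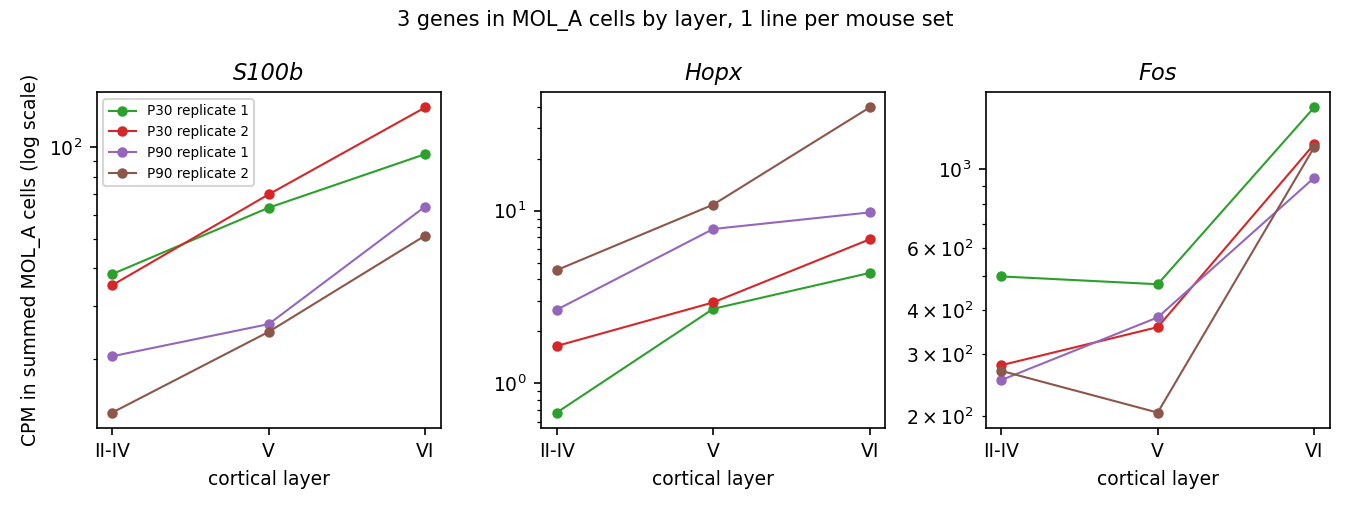
CPM of S100b, Hopx and Fos in summed MOL_A cells (vertical axis, logarithmic) by cortical layer (horizontal axis), with 1 line per mouse set (4 sets). S100b averaged 26.8 CPM in layers II-IV, 46.0 in layer V and 86.4 in layer VI.

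In MOL_A, 23 of 24 immediate early and dissociation genes rose in layer VI against layers II-IV and 22 of 24 against layer V (23 and 23 adjusted over the list alone), such as Egr1 (1.86 ± 0.11 and 2.01 ± 0.11). Their camera adjusted p was 1.5e-31 and 4.83e-30, with adjusted p = 0.0164 and 0.0373 with an estimated correlation, so both calls held. Of 23 cholesterol synthesis genes 14 and 5 rose (19 and 15 adjusted over the list alone; camera adjusted p = 7.94e-12 and 1.52e-06), with adjusted p = 0.0164 and 0.0569 with an estimated correlation. Mature oligodendrocyte markers went both ways in layer VI against layers II-IV, 8 rising and 4 falling of 18 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0413, and adjusted p = 0.557 with an estimated correlation). Of them 4 rose in layer V against layers II-IV (10 higher and 2 lower adjusted over the list alone; 0.000186, and adjusted p = 0.328 with an estimated correlation). Of 15 immature neuron genes 4 rose in layer VI against layers II-IV, such as the tubulin gene Tubb3 (0.76 ± 0.09), and 2 against layer V (6 and 5 adjusted over the list alone; camera adjusted p = 0.00218 and 0.00842, with adjusted p = 0.154 and 0.184 with an estimated correlation). By edgeR 690 of 11552 genes passed in layer VI against layers II-IV (391 higher and 299 lower), 229 against layer V (159 higher and 70 lower) and 30 in layer V against layers II-IV (23 higher and 7 lower). DESeq2 called 386, 102 and 6. In layer VI against layers II-IV 247 passed without P30 replicate 2 and 302 without P90 replicate 2, and against layer V 111 and 75. In layer V against layers II-IV 10 passed without P30 replicate 1, 12 without P90 replicate 1 and 18 without P90 replicate 2.

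Within OPC alone, a comparison chosen after seeing the data, few genes passed. Bmp4, a signal expressed as precursors commit to differentiation (chromosome 14, 46383520 to 46390669), rose in layer VI against layers II-IV by 1.28 ± 0.18 (n = 5 sets; edgeR adjusted p = 0.000262), at 31.1 ± 14.5 against 14.6 ± 11.9 CPM. The homeobox gene Dbx2 rose by 1.03 ± 0.14 and Insig1, a regulator of sterol synthesis, by 0.58 ± 0.11. Col19a1, a collagen gene (chromosome 1, 24261890 to 24587472), differed by -2.60 ± 0.32 (adjusted p = 0.000131), and the transcription factor genes Otx1 and Nr4a1 by -1.36 ± 0.18 and -0.59 ± 0.08. Of 20 cell cycle genes 1 rose in layer VI against layers II-IV and 0 against layer V (12 and 10 higher adjusted over the list alone). Their camera adjusted p was 6.86e-06 and 6.68e-07, with adjusted p = 0.367 and 0.504 with an estimated correlation. Cholesterol synthesis was shifted up in layer VI against layers II-IV (1 of 23 rose, 5 adjusted over the list alone; camera adjusted p = 8.68e-09, and adjusted p = 0.3 with an estimated correlation). It was also shifted up in layer V against layers II-IV (0 passed; 3.86e-05, and adjusted p = 0.897 with an estimated correlation). By edgeR 74 of 12226 genes passed in layer VI against layers II-IV, 9 against layer V and 0 in layer V against layers II-IV (777 at unadjusted p under 0.05), and DESeq2 called 62, 7 and 0. In layer VI against layers II-IV 142 passed without P7 replicate 1 and 45 without P90 replicate 1, and against layer V 15 without P30 replicate 1 and 3 without P30 replicate 2. In layer V against layers II-IV 26 passed without P14 replicate 1, 3 without P7 replicate 1 and 1 without each of P30 replicate 1, P30 replicate 2 and P90 replicate 1.

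Across age, from P7 to P90, no gene of the summed lineage cells passed with the chemistry as a covariate. By edgeR 0 of 14349 passed (1620 at unadjusted p under 0.05; n = 6 sets), and DESeq2 called 436. The smallest p belonged to Gpx3 at -1.66 ± 0.17 and Sox9 at -2.07 ± 0.22 per doubling of age (adjusted p = 0.179 and 0.179) on the lower side, and Kif13b at 1.28 ± 0.17 (adjusted p = 0.233) and Anln at 1.36 ± 0.23 on the higher. Mature oligodendrocyte markers were shifted up with age (4 of 18 higher adjusted over the list alone; camera adjusted p = 2.25e-09), and cell cycle (10 of 20 lower adjusted over the list alone; 2.05e-09) and immature neuron genes (4 of 19; 1.36e-05) down. These 3 had adjusted p = 0.472 with an estimated correlation. Cholesterol synthesis (2 of 23 lower adjusted over the list alone; camera adjusted p = 1.91e-07) and precursor and newly formed oligodendrocyte markers (0 of 14; 0.00688) were shifted down, with adjusted p = 0.729 with an estimated correlation. Myelin and immediate early genes were shifted up (camera adjusted p = 0.0137 and 0.000917), with adjusted p = 0.749 and 0.472 with an estimated correlation. P90 replicate 2, 1 of the 2 oldest sets, held 1 OPC among 8177 cells and 77.5 to 91.9% MOL_A per library, and these list shifts include that difference in classes. Neuron and mural markers were shifted down (camera adjusted p = 0.0448 and 0.0183), with adjusted p = 0.729 and 0.472 with an estimated correlation. P7 replicate 1 alone held high values of several neuronal genes. Stmn2 was at 129 CPM there and at most 1.08 in any other set, Cd24a at 33.9 and 2.45, Nrgn at 44.4 and 7.40, and Rbfox3 at 5.73 and 0.603. Syt1 differed less (16.6 and 8.26), and the immature neuron genes Tmsb10 and Marcksl1 were highest in P14 replicate 1. Of the mural genes named by rule none exceeded 1.58 CPM. Leaving out P30 replicate 2 or P90 replicate 2 gave 113 or 98 genes, and taking the 18 layer libraries as samples, although the 3 layers of a set share mice, gave 5483.

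The change of the layer VI against layers II-IV difference with age was tested as an interaction. Cxcl12, a chemokine that guides migrating cells (chromosome 6, 117168535 to 117181367), differed by -1.63 ± 0.15 per doubling of age (edgeR adjusted p = 0.000708, n = 6 sets) and Inppl1, an inositol phosphatase gene (chromosome 7, 101822632 to 101838229), by -0.68 ± 0.09 (adjusted p = 0.0357). Hopx was at 1.12 ± 0.22 (adjusted p = 0.181). Class shares enter these sums, with COP 17.0 points higher in layer VI than in layers II-IV in P7 replicate 1, and MFOL 15.6 and NFOL 5.07 points higher in P14 replicate 1, each apart from the other sets. Precursor and newly formed oligodendrocyte markers were shifted down (9 of 14 lower adjusted over the list alone; camera adjusted p = 1.07e-09, and adjusted p = 0.0856 with an estimated correlation). So were myelin genes (0 passing adjusted over the list alone; 3.96e-05, and adjusted p = 0.719 with an estimated correlation). Immediate early genes (1.07e-09), mature oligodendrocyte (0.00113), neuron (0.00113), astrocyte (0.00397) and endothelial markers (camera adjusted p = 0.0314) were shifted up, with adjusted p = 0.595 with an estimated correlation. By edgeR 2 genes passed and by DESeq2 38; 0 passed without P14 replicate 1, without P90 replicate 2 or without the block (705, 749 and 52 at unadjusted p under 0.05), 1 without P30 replicate 1 and 122 without P90 replicate 1.

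In whole S1 the classes of cells were compared between P21 and P7. Myelin-forming oligodendrocytes (MFOL) made up 16.6 ± 0.695% of deposited cells at P21 (SD, n = 4 libraries) and mature oligodendrocytes (MOL) 28.9 ± 1.5%, against 0 of 15985 cells at P7 for each. Neither name is among the authors' classes at P7, so these shares were set to 0. An upper limit of 0.0188% at P7, and the tests of these 2 classes, hold only if such cells would have been given these names there. NFOL rose to 6.03 ± 0.121% from 1.31 ± 0.0959% (n = 3) and committed precursors (COP) to 8.03 ± 0.525% from 6.29 ± 0.180%, while OPC fell to 18.6 ± 0.944% from 26.8 ± 0.868%. All 7 neuron classes took smaller shares at P21, such as layer 4 neurons (L4, 5.94 ± 0.239% against 19.2 ± 0.771%), upper layer callosal neurons (UL_CPN, 6.06 ± 0.398% against 17.4 ± 0.161%) and corticothalamic neurons (CThPN, 4.06 ± 0.377% against 14.6 ± 0.136%). Each of the 12 classes had a two-sided exact permutation p of 0.0286, the smallest that 4 against 3 libraries allow, and an adjusted p of 0.0286. Among neurons alone, a denominator chosen after seeing the data, 0 of 7 classes passed by the exact permutation test (3 at unadjusted p under 0.05), and near-projecting neurons (NP/SCPN) were at 4.09 against 2.03%, deep layer callosal neurons (DL_CPN) at 20.3 against 15.6%. Intervals and limits here cover counting error only.

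Gene expression in all projection neurons was compared between P21 and P7. Nrn1, a secreted protein that promotes neurite growth (chromosome 13, 36725361 to 36735131), rose by 3.35 ± 0.03, to 809.8 ± 9.29 from 79.6 ± 2.77 CPM (n = 4 and 3 libraries; edgeR adjusted p = 4.34e-15). Hapln4, of the matrix around axons and synapses, rose by 6.54 ± 0.08. Dpysl3, a growth cone protein (chromosome 18, 43320984 to 43438286), differed by -6.19 ± 0.04, at 11.3 ± 0.813 against 826 ± 7.76 CPM (adjusted p = 2.87e-16), the tubulin gene Tubb2b by -10.12 ± 0.11 and the growth-associated Gap43 by -2.89 ± 0.03. Of the 3 cue genes fixed beforehand, Fgf18 (chromosome 11, 33117430 to 33147400) differed by -1.91 ± 0.23, at 0.420 ± 0.0841 against 1.58 ± 0.138 CPM, and the cell adhesion gene Ncam1 (chromosome 9, 49502136 to 49798925) by -1.81 ± 0.03, at 207 ± 8.86 against 725 ± 16.7. The R-spondin gene Rspo3 (chromosome 10, 29452416 to 29535867) rose by 1.19 ± 0.04, to 49.3 ± 3.05 from 21.5 ± 0.220 CPM (adjusted p = 8.4e-06, 4.88e-13 and 1.42e-10). Xist, which is expressed from the inactive X chromosome of females, was at 365 ± 8.60 CPM at P21 and 0.158 at P7, while Y-linked genes had counts at both ages; of 12889 autosomal genes tested 10723 passed.

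Mature neuron genes rose and immature ones fell between P7 and P21. Of 20 mature neuron genes 19 rose and 1 fell (camera adjusted p = 1.14e-05, and adjusted p = 0.196 with an estimated correlation), such as Snap25 (1.92 ± 0.02) and Camk2n1 (2.94 ± 0.04). Of 20 immature neuron genes 1 rose and 19 fell (camera adjusted p = 2.16e-07; adjusted p = 0.0349 with an estimated correlation, so the call held). Cholesterol synthesis genes fell in 20 of 23 cases and rose in 1, with Sqle at -2.38 ± 0.03 and Hmgcs1 at -1.92 ± 0.03 (camera adjusted p = 4e-06, and adjusted p = 0.0859 with an estimated correlation). All 12 measured microglia markers rose, such as C1qa (4.40 ± 0.25; camera adjusted p = 0.000759, and adjusted p = 0.771 with an estimated correlation). Layer 4 neuron markers rose in 7 of 8 cases and fell in 1 (camera adjusted p = 0.0445, and adjusted p = 0.254 with an estimated correlation). The neuronal cues, 27 rising and 23 falling of 54, and their receptors, 14 and 12 of 32, were not called as lists (camera adjusted p = 0.926 and 0.926), and in both the median (0.08 and 0.14) and the mean (-0.10 and -0.25) differ in sign.

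The remaining lists were not called between the ages, although many members passed. Rising and falling members were 2 and 5 of 8 OPC markers (camera adjusted p = 0.586), 4 and 4 of 9 precursor and newly formed oligodendrocyte markers (0.926), 10 and 3 of 13 myelin genes (0.235), and 7 and 5 of 17 mature oligodendrocyte markers (0.926). They were 10 and 10 of 23 immediate early genes (0.926), 9 and 2 of 12 interferon genes (0.118), and 4 and 6 of 13 cell cycle genes (0.443). Neuron subtype markers gave 3 and 6 of 10 (upper layer callosal, 0.405), 2 and 7 of 12 (layer 5 subcerebral, 0.337), 2 and 7 of 10 (layer 6 corticothalamic, 0.259), 1 and 7 of 8 (layer 6b and near-projecting, 0.0856), 3 and 5 of 10 (inhibitory, 0.926) and 6 and 8 of 15 (neuron markers, 0.926). Markers of other tissue cells gave 7 and 2 of 11 (astrocyte, 0.259), 2 and 1 of 4 (endothelial, 0.926) and 1 and 1 of 3 (mural and fibroblast, 0.926). Median, mean or test differ in sign for the precursor and newly formed, mature oligodendrocyte, inhibitory and mural lists. Adjusted over the list alone, 6 mature oligodendrocyte markers rose, and every other list had the number given. By edgeR 11474 of 13777 genes passed, 5689 higher and 5785 lower.

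In OPC of whole S1, Htra1, a secreted serine protease (chromosome 7, 130936111 to 130985660), rose between P7 and P21 by 4.63 ± 0.07, to 489 ± 17.2 from 19.7 ± 1.57 CPM (edgeR adjusted p = 6.6e-16; n = 4 and 3 libraries). Fabp7, a fatty acid carrier of immature glia (chromosome 10, 57784881 to 57788450), differed by -2.32 ± 0.04 and the glial transcription factor Sox9 by -3.15 ± 0.08. All 23 measured cholesterol synthesis genes but 1 fell, such as Fdft1 (-1.60 ± 0.07; camera adjusted p = 4.74e-10), 18 of 22 immediate early genes rose and 1 fell (8.67e-07), and 12 of 13 interferon genes rose (1.44e-05). These calls held, with adjusted p = 0.0359, 0.0359 and 0.0449 with an estimated correlation. Without OPC that hold a microglial UMI, chosen after seeing the data, 8 of 11 interferon genes rose and 1 fell, 8 of 11 myelin genes rose, and of 20 cell cycle genes 11 fell and 3 rose. OPC markers rose in 9 of 10 cases, such as Vcan (1.83 ± 0.05), and myelin genes in 14 of 17 (camera adjusted p = 0.000608 and 0.000111), with adjusted p = 0.0654 and 0.146 with an estimated correlation. The OPC sums were not corrected for RNA carried over from mature oligodendrocytes, a class the authors named at P21 alone. Cell cycle genes fell in 17 of 20 cases, such as Mcm6 (-2.35 ± 0.11), and all 12 microglia markers rose, such as C1qc (8.46 ± 0.30; camera adjusted p = 4.25e-06 and 2.35e-08), with adjusted p = 0.146 with an estimated correlation for both. Adjusted over the list alone, the numbers were the same except for immediate early genes (19 higher, 2 lower). Counts per class were 7150 genes in OPC, 5864 in COP, 4069 in NFOL, 9409 in UL_CPN, 8626 in L4, 8898 in DL_CPN, 7717 in CThPN, 4412 in subcerebral neurons (SCPN) and 4313 in NP/SCPN.

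Deep projection neurons (DL_CPN, CThPN, SCPN and NP/SCPN) were compared with upper ones (UL_CPN and L4) within the same libraries. At P7, Rprm, a layer 6 marker gene (chromosome 2, 54084093 to 54085552), was higher in deep neurons by 2.67 ± 0.02 (n = 3; edgeR adjusted p = 6.59e-30) and Bcl11b, which specifies subcerebral neurons, by 5.68 ± 0.04. Cux2, a transcription factor of upper layers (chromosome 5, 121856366 to 122050102), differed by -4.24 ± 0.05 and the growth factor gene Ptn by -3.21 ± 0.02. At P21, Pcp4, a calmodulin regulator (chromosome 16, 96467606 to 96525793), was higher in deep neurons by 4.10 ± 0.04 (n = 4) and Fezf2 by 4.96 ± 0.08, while Calb1, a calcium buffer (chromosome 4, 15881264 to 15908064), differed by -4.97 ± 0.05. Of the cue genes, Rspo3 was lower in deep neurons at P7 (-0.72 ± 0.05, at 15.2 ± 0.716 against 25.1 ± 0.505 CPM) and P21 (-0.45 ± 0.07, at 42.5 ± 5.26 against 57.8 ± 2.75 CPM). Ncam1 differed by -0.11 ± 0.01 at P7 and 0.40 ± 0.03 at P21, and the change between the ages passed as an interaction for both genes (0.51 ± 0.03 and 0.27 ± 0.08; edgeR adjusted p = 5.55e-12 and 0.0111). The mix of classes in the deep sums also differed between the ages, so these interactions may not lie within a class. Fgf18 was at 0.43 ± 0.19 at P7 (edgeR adjusted p = 0.0576).

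The cue genes depended on which classes were compared. For the layer 5 classes against the layer 2 to 3 class, Fgf18 at P7 was 1.83 (edgeR adjusted p = 9.55e-08), Ncam1 -0.04 (edgeR adjusted p = 0.28) and Rspo3 -1.61 (edgeR adjusted p = 2.01e-18). Without P7 replicate 2, Fgf18 in deep against upper neurons passed at 0.65 (edgeR adjusted p = 0.0192). Over all alternatives at P7 the adjusted p ran from 9.55e-08 to 0.396 for Fgf18, from 3.68e-13 to 0.28 for Ncam1 and from 7.31e-39 to 2.93e-08 for Rspo3 (edgeR or DESeq2). Per class at P7, Fgf18 averaged 5.77 ± 1.24 CPM in SCPN and 6.66 ± 1.60 in NP/SCPN (SD, n = 3), against 1.67 ± 0.151 in UL_CPN, 1.29 ± 0.495 in DL_CPN and 0.972 ± 0.0861 in CThPN. Ncam1 at P21 averaged 558 ± 82.7 CPM in NP/SCPN, 273 ± 17.9 in CThPN and 134 ± 2.80 in L4. Rspo3 averaged 39.9 ± 1.20 CPM in UL_CPN and 9.18 ± 0.367 in L4 at P7, and 51.4 ± 4.25 and 65.6 ± 2.56 at P21. Differences between single classes were not tested.

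**Figure D3:**
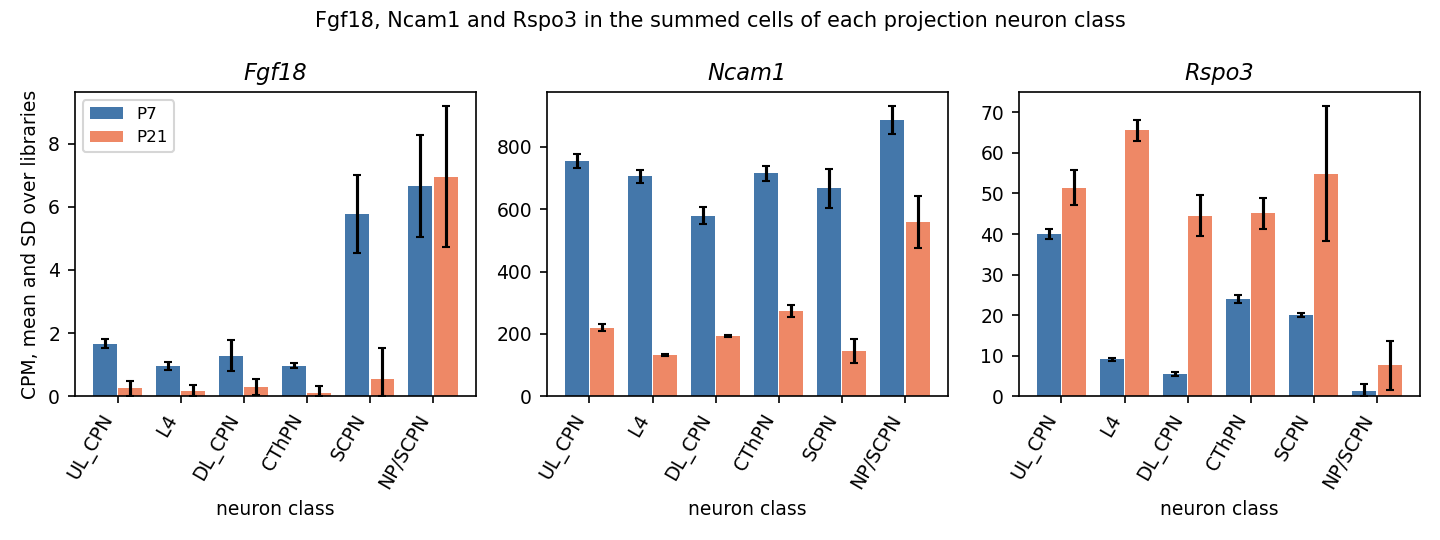
CPM of Fgf18, Ncam1 and Rspo3 (vertical axes, each from 0) in the summed cells of 6 projection neuron classes (horizontal axis) at P7 (blue) and P21 (orange). Bars give the mean and error bars the SD over 3 libraries at P7 and 4 at P21 (3 for SCPN); Fgf18 at P7 was 5.77 CPM in SCPN and 1.67 in UL_CPN.

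Lists of layer identity differed between deep and upper neurons in the direction of their names. The neurons were grouped by the authors' class names, and whether these markers served to assign them is not given in the sources used here, so these lists are no independent test. At P7 and P21, 10 and 10 of 10 layer 6 corticothalamic markers were higher in deep neurons (camera adjusted p = 1.32e-06 and 1e-07), and 9 and 8 of 10 upper layer callosal markers lower (5.87e-05 and 3.45e-05). For both lists adjusted p = 0.606 at P7 and 0.128 at P21 with an estimated correlation. Layer 4 markers were lower in 6 and 7 of 8 cases and higher in 1 and 1 (camera adjusted p = 0.0473 and 0.000292; adjusted p = 0.606 and 0.306 with an estimated correlation). Layer 6b and near-projecting markers were higher in 7 of 8 and 7 of 7 (0.000655 and 0.000219; adjusted p = 0.606 and 0.306 with an estimated correlation). Cholesterol synthesis genes were higher in 15 and 21 of 23 cases and lower in 1 and 0, with Hmgcs1 at 0.95 ± 0.04 at P21 (camera adjusted p = 0.000655 and 2.96e-06; adjusted p = 0.759 and 0.128 with an estimated correlation). In the layer 5 classes against the layer 2 to 3 class at P7, 3 of the 4 cholesterol synthesis genes named by rule were instead lower, Fdps (-0.46), Sqle (-0.67) and Fdft1 (-0.58). Immediate early genes were higher in 16 and 12 of 23 and lower in 2 and 3 (camera adjusted p = 0.000655 and 0.0252; adjusted p = 0.705 and 0.29 with an estimated correlation). Of these, Btg2 (-0.20) and Nr4a2 (-0.84) were instead lower in the layer 5 classes against the layer 2 to 3 class at P7. At P21, 9 of 12 layer 5 markers were higher and 1 lower, all 12 microglia markers higher, and of 20 mature neuron genes 13 lower and 4 higher (camera adjusted p = 0.00174, 0.000652 and 0.0201), with adjusted p = 0.29, 0.586 and 0.586 with an estimated correlation. The inhibitory list was called at P7, 8 of 12 higher and 1 lower (0.00606, and adjusted p = 0.606 with an estimated correlation), with the neuropeptide gene Npy at 3.53 ± 0.04. Neuronal cues gave 27 higher and 19 lower of 54 at P7 (28 and 19 adjusted over the list alone) and 26 and 18 of 49 at P21 (27 and 18 adjusted over the list alone), and were not called as a list (0.249 and 0.205). Adjusted over the list alone, counts of the other lists named here were the same except 1 more immediate early gene lower at P7 and 1 more layer 5 marker lower at P21. By edgeR 9010 of 14744 genes passed at P7 (4544 higher and 4466 lower) and 6910 of 12759 at P21 (3611 higher and 3299 lower), and DESeq2 called 5785 and 4070.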

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

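In this part the tests of tissue handling, of another class name, of chemistry and of removal, the counts over other splits, and the tests of MOL_A against OPC and of deep against upper neurons between ages were chosen after the result was seen.

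Chance picks out about 1 in 20 groups of values as having a sample far from the others, and 32 of the 272 groups tested had one. That rate takes the samples of a group as replicates. The 6 sorted sets differ in age and chemistry, and P7 and P14 have 1 set each. A sorted set that stands apart can therefore not be told apart from an effect of its age or chemistry. Among differences in class shares, P7 replicate 1 stood apart for COP, with layer VI minus layers II-IV at 17.0 points and layer VI minus layer V at 16.8. P14 replicate 1 stood apart for MFOL (5.79 for layer V minus layers II-IV, 15.6 for layer VI minus layers II-IV and 9.85 for layer VI minus layer V) and NFOL (5.07 for layer VI minus layers II-IV and 3.99 for layer VI minus layer V). P30 replicate 2 stood apart for MOL_B (layer V minus layers II-IV, 4.54) and MOL_C (layer VI minus layers II-IV, 7.05, and layer VI minus layer V, 4.99).

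Single sets stood apart in the log2 difference of genes. In layer V against layers II-IV these were Apoe in P30 replicate 2 (-1.58) and Fgfr3 in P7 replicate 1 (-0.87). In layer VI against layers II-IV, P7 replicate 1 was low for Tmem117 (0.29), Cd59a (0.01003) and Atf3 (-0.0649), and P90 replicate 2 for Pdgfa (0.45). P30 replicate 2 had the lowest values for Xylt1 (-2.12), Ptprz1 (-2.21), Slc1a2 (-2.04) and Scn1a (-2.15). In layer VI against layer V, Csrnp1 stood apart in P7 replicate 1 (0.19), Rab4a in P90 replicate 1 (1.29), Peg3 in P14 replicate 1 (-0.72), Cspg4 and Snap25 in P90 replicate 2 (0.14 and 0.40) and B2m in P30 replicate 1 (-0.82). Among P21 libraries, deep against upper neurons gave S100a6 at -3.72 and the microglial gene Trem2 at 2.55 in replicate 4 and Cplx3 at 2.95 in replicate 3. In all P21 neurons, on CPM scaled by TMM, Plppr1 was at 6.00 in replicate 4, Camk2n1 at 1892 in replicate 1 and Fgf18 at 0.287 in replicate 2. Without that scaling they were at 6.15, 1929 and 0.294 CPM.

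Differences between groups were tested directly. The layer VI minus layers II-IV difference had a slope on log2 age of -1.63 for Cxcl12 and -0.68 for Inppl1, the 2 genes that passed, but 0 passed by edgeR without P14 replicate 1 or without P90 replicate 2 (705 and 749 at unadjusted p under 0.05), and chance could not be excluded for this count by other splits. The deep minus upper difference changed between P7 and P21 for 5853 genes, including Ncam1 (0.51) and Rspo3 (0.27). The mix of classes in the deep sums also differed between these ages. Between MOL_A and OPC the layer VI minus layers II-IV difference was not the same for 52 of 12407 genes over 3 sets, and 15 immediate early genes were among those larger in MOL_A.

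Immediate early genes were higher in MOL_A cells of layer VI than of layers II-IV. In the 3 sets with both classes the list's median was 1.09 in MOL_A and -0.31 in OPC, with a median difference of 1.58 (SE 0.16 over genes). That SE does not measure the spread between mice. Tested gene by gene over the 3 sets, 15 of 23 were larger in MOL_A and 0 smaller. These values argue against handling of the layer VI tissue that acts on all classes alike. MOL_B cells counted among MOL_A could not be excluded as a cause in MOL_A. The immediate early genes need 12.2 to 18.1% of such cells (quartiles of 20 genes), not above the 16.0 to 28.8% that 124 other MOL_B genes need. The medians were 15.5 and 22.6%. Such cells would not raise the list within MOL_B itself, where its median was 0.61, with 4 of 22 genes higher and 0 lower. A response of mature cells in layer VI to their neighbours, or to handling in that class alone, stays open and was not tested.

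OPC were missing from P90 replicate 2, with 1 OPC among 8177 cells of its 3 libraries. Another class name for these cells is argued against, since the median OPC marker lay at 0.167% or less of its level in P90 replicate 1. Chemistry as the whole cause is argued against by P30 replicate 2, where OPC made up at least 11.6% of each library. Removal of OPC in the sort or by the filter on cells, where this 1 cell is all there is to count, cannot be told apart from their absence, because no unsorted or unfiltered cells of these mice were analysed here. No biological explanation was tested.

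Microglial transcripts were present in the P21 sums of OPC and neurons. Free RNA shared by all droplets of a library is argued against, since OPC held 2.43 to 6.00 times as many microglial UMIs per cell as neurons in the 4 libraries. A few cells holding a microglial cell's RNA is a candidate explanation, as 97.4 to 100% of the microglial UMIs of OPC lay in the tenth of OPC with most. Without OPC holding a microglial UMI, 6220 of 10921 genes passed between P21 and P7, 5870 of them among the 7150 called with all OPC. No biological explanation was tested.

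Other splits of the same samples were counted. For layer comparisons layers were exchanged within sets, 100 splits each, and the counts below are the splits with as many genes as the real one. A share under 0.05 was taken to argue against chance, without adjustment over the comparisons and from a sample of the possible layer splits. It was reached for layer VI against layers II-IV, with 1 of 100 (4057 genes in the real split, 2849 in the highest other), and for layer VI against layer V, with 1 of 100 (17 genes in the real split, 0 in the highest other). It was also reached for the same comparisons in MOL_A, with 1 of 100 (690 genes in the real split, 603 in the highest other) and 3 of 100 (229 genes in the real split, 690 in the highest other). In OPC it was reached for layer VI against layers II-IV, with 1 of 100 and a narrow margin (74 genes in the real split, 67 in the highest other). Chance could not be excluded for layer V against layers II-IV in MOL_A, with 11 of 100 (30 genes in the real split, 690 in the highest other), or for layer VI against layer V in OPC, with 7 of 100 (9 genes in the real split, 67 in the highest other). For these 2 the splits cannot decide, since some carry the difference of layer VI from layers II-IV. Nor could chance be excluded for the interaction of layer with age, with 15 of 100 (2 genes in the real split, 469 in the highest other). Where the real split called 0 genes (edgeR), all 100 of 100 splits give as many by design, so the count says nothing about chance. This holds for layer V against layers II-IV over all cells (0 and 7 in the real and the highest other split; 1575 at unadjusted p under 0.05, and 1 by DESeq2), for the same comparison in OPC (0 and 58; 777 at unadjusted p under 0.05, and 0 by DESeq2) and for the age trend (0 and 0; 1620 at unadjusted p under 0.05, and 436 by DESeq2). The layer splits exchange all 3 layers, so some set layer VI libraries against those of layers II-IV under another name. The highest in MOL_A, 690, equalled the count of that comparison there. Splits with several times the real count can thus carry the layer VI difference. This concerns layer V against layers II-IV and layer VI against layer V in MOL_A, and layer VI against layer V in OPC. For the interaction, splits with more genes than the real one were not tested further. Between P21 and P7, 1 of 35 splits, the real one, gave as many genes. This argues only against a chance spread between these libraries, since nothing shows that those of an age came from separate animals. Age cannot be told apart from sex, as Xist was nearly absent at P7 but not at P21, or from anything else that differed between the ages. The real and the highest other split had 11474 and 6 genes in neurons. In oligodendrocyte classes they were OPC (7150 and 1), COP (5864 and 1), and NFOL (4069 and 0). In neuron classes they were UL_CPN (9409 and 10), L4 (8626 and 13), DL_CPN (8898 and 0), CThPN (7717 and 2), NP/SCPN (4313 and 1618; the other split set P21 replicate 4 with the P7 libraries) and the change of the deep against upper difference (5853 and 71). The splits were too few for a share under 0.05 in SCPN (10 splits, 4412 and 0), deep against upper neurons at P7 (4 splits, 9010 and 0) and at P21 (8 splits, 6910 and 0).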

How the results depend on the processing

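The settings with OPC alone, all mature classes, neurons alone as denominator, the cell number test, the subplate class among deep neurons, OPC without microglial UMIs and no block in the interaction were chosen after seeing the data, as were all settings of the comparisons within MOL_A, within OPC and of the deep against upper change. The rest were fixed before. Over all values given by a fixed setting, 4693 kept their direction and side of the threshold or stayed within the spread or 1.5 times the count, 342 lost and 158 gained significance, 49 counts or values moved and 10 reversed; for settings added later these were 392, 57, 33, 50 and 12. The P21 against P7 counts in neurons and in each class and the deep against upper counts, apart from those named below, stayed within 1.5 times. Except where fewer samples, genes or counts entered, the cause was not tested.

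Counts of genes below are for layer VI against layers II-IV, layer VI against layer V and layer V against layers II-IV, in this order, where 3 stand together. Over all cells, with age in place of the mouse set as a replicate block, they were 0, 0 and 0 (edgeR; 376, 114 and 28 at unadjusted p under 0.05), in MOL_A 3, 0 and 0, in OPC 0, 0 and 0, and 0 for the interaction with age. Leaving out 1 set gave 1918 to 4275, 0 to 69 and 0 throughout over all cells, 247 to 745, 75 to 218 and 10 to 22 in MOL_A, 45 to 142, 3 to 15 and 1 to 26 in OPC, 0 to 113 for the age trend and 0 to 122 for the interaction. Only replicate 1 sets gave 2248 and 129 for the comparisons of layer VI, only replicate 2 sets 754 and 12, and only P30 and P90 2505 and 33. MOL_A cells alone gave 690, 229 and 30, all mature classes 1199, 607 and 38, and OPC alone 74 and 9. With the immediate early score as a covariate the counts were 217, 0 and 1 over all cells and 27 and 12 in MOL_A. DESeq2 called 398 and 1 in the last 2 over all cells, and 386, 102 and 6 in MOL_A. Without a filter on low counts they were 102 and 1 in the last 2 over all cells, 70 for layer V against layers II-IV in MOL_A, and 351, 119 and 125 in OPC. Depth limits these counts: thinned to the smallest total they were 381, 1 and 0 over all cells, 1, 0 and 0 in MOL_A and 0, 0 and 0 in OPC, 0 for the interaction and 2129 for the change of the deep against upper difference.

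For the age trend, the 18 layer libraries as samples gave 5483 genes, MOL_A cells 398, OPC 678 and DESeq2 436, and P90 against P30 with the replicate block 0 (270 at unadjusted p under 0.05). For its interaction with layer MOL_A gave 10, OPC 6 and DESeq2 38. Deep against upper neurons gave 5785 at P7 and 4070 at P21 by DESeq2. Of the gene list calls 62 became 1 with an estimated correlation. Whole S1 libraries share replicate numbers, but the deviations of same-numbered libraries had correlations across genes of 0.0889, -0.0686 and 0.0425, so the numbers do not pair them; with the number as a replicate block 12039 genes passed in neurons. Of the shares by layer 0 passed as shares, as log odds or of all deposited cells, and 2 by the edgeR test of cell numbers. The smallest exact sign-flip p of the shares was 0.0625, where 0.0312 was the smallest possible with 6 sets that differ. For MOL_B, with 1 set at a difference of 0, 0.0625 was the smallest possible. A single test at 0.0312 could not pass after adjustment over 21 tests. Of the shares between ages 12 passed of all deposited cells and 0 of neurons alone, where the differences of DL_CPN, NP/SCPN and UL_CPN reversed to 4.75, 2.06 and 1.15 points.

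Named genes reversed in these settings. In layer VI against layers II-IV they were, in OPC alone, Cd59a (-0.15), Errfi1 (-0.17) and Ugt8a (-0.0142), in MOL_A alone Ugt8a (-0.0402) and Fgfr2 (-0.0138), and over all mature classes Gsta4 (0.0480), Myrf (-0.0128), Slc1a3 (0.13) and Snap25 (0.0638). In layer VI against layer V they were Atf3 (-0.17) and Zfp36 (-0.33) in OPC alone. Rspo1 was at -0.20 between P21 and P7 in deep neurons alone. In deep against upper neurons at P7, the layer 5 classes against the layer 2 to 3 class gave Cck -0.83, Rorb 0.40, Fdps -0.46, Sqle -0.67, Fdft1 -0.58, Btg2 -0.20 and Nr4a2 -0.84.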

Other observations

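In this part the comparisons within single classes, between MOL_A and OPC, and of deep against upper neurons between ages were chosen after the result was seen.

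Other lists moved within single classes of layer VI. In OPC of layer VI against layers II-IV (n = 5 sets), 2 of 19 myelin genes rose, without a correction for RNA carried over from mature cells, with 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0428, and adjusted p = 0.426 with an estimated correlation). In MOL_A, MOL_B and MOL_C 0 of 19 rose by edgeR, and 1, 2 and 0 fell. In OPC, of 19 immature neuron genes 2 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.000859, and adjusted p = 0.3 with an estimated correlation), and Bcl11b, a transcription factor known from deep layer neurons, rose by 1.57 ± 0.35. Against layer V, OPC of layer VI were higher in Gpnmb (1.47 ± 0.23) and Gap43 (0.43 ± 0.08) and lower in the transcription factor gene Zfhx4 (-0.87 ± 0.16). Cholesterol synthesis genes rose in layer VI against layers II-IV in 10 of 23 cases in MOL_C and 5 of 22 in MOL_B, with list medians of 0.49 and 0.45 (edgeR, n = 4 sets). Immediate early genes rose in 12 of 19 in MOL_C and 4 of 22 in MOL_B, and 1 fell and 0 rose of 22 in OPC. Between MOL_A and OPC the layer difference was larger in MOL_A for Fos (2.41 ± 0.18), Egr1 (2.42 ± 0.24) and Uchl1, a neuronal ubiquitin hydrolase (2.40 ± 0.22; n = 3 sets).

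The difference between deep and upper neurons itself changed between P7 and P21. The mix of classes in the deep sums differed as well. Of all neurons, CThPN made up 22.2% at P7 and 18.5% at P21, DL_CPN 15.6 and 20.3%, and NP/SCPN 2.03 and 4.09%. A change within classes cannot be told apart from this difference in mix here. It moved toward deep neurons for Pde1a, a calmodulin-dependent phosphodiesterase (chromosome 2, 79834453 to 80129458), by 3.25 ± 0.04 (edgeR adjusted p = 4.79e-25; n = 4 and 3 libraries) and for the imprinted gene Nnat by 3.19 ± 0.10. It moved by -2.01 ± 0.03 for the neuropeptide gene Cck and by -3.63 ± 0.09 for Nptx1, which clusters glutamate receptors. Of 23 cholesterol synthesis genes 16 moved toward deep and 1 toward upper neurons (16 and 2 adjusted over the list alone; camera adjusted p = 0.00168, and adjusted p = 0.346 with an estimated correlation). Of 20 immature neuron genes 17 moved toward deep neurons and 1 toward upper ones (camera adjusted p = 2.93e-05, and adjusted p = 0.346 with an estimated correlation), and of 23 immediate early genes 4 and 12 (camera adjusted p = 0.0445, and adjusted p = 0.408 with an estimated correlation), with Arc at -1.60 ± 0.06.

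Genes of the sex chromosomes differed between sets. Xist was at 0 to 0.681 CPM in the P14 replicate 1 and P30 replicate 2 libraries, while the libraries of the other sorted sets held both Xist and Y-linked genes. The labels give 1 male and 1 female mouse per time point, and these values go against a female mouse in those sets. In whole S1 Xist was at 0.130 to 0.193 CPM at P7 and 455 to 480.0 at P21, and Y-linked genes had counts at both ages.

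In P21 libraries, microglial UMIs averaged 12.1 ± 3.16 per OPC, 13.3 ± 1.08 per COP, 7.09 ± 2.32 per DL_CPN and 0.864 ± 0.390 per L4 cell (SD, n = 4). Without OPC that hold a microglial UMI, cholesterol synthesis genes fell between P7 and P21 in 21 of 23 cases, and immediate early genes rose in 13 and fell in 3 of 20. Interferon and MHC class I genes rose in 8 and fell in 1 of 11, and myelin genes rose in 8 of 11. Cell cycle genes fell in 11 and rose in 3 of 20, where 17 fell with all OPC.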
